A study of Mus musculus with 8 samples.

How the data were processed

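Gene expression was measured on 8 one-colour Illumina bead arrays, 1 per RNA sample, in λ820 cells, a mouse lymphoma line driven by Myc. Per the labels' protocols, the cells grew in RPMI with fetal bovine serum. They were kept for 24 h with the solvent DMSO (diluted 1000-fold) or with a drug at 10 µM, either RVX2135 or VE-821, or with both drugs together. RNA was prepared with a Nucleospin kit and labelled with biotin, per the labels' protocols. Each of the 4 groups had 2 arrays, and the group and replicate number of each array came from its title. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

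The authors deposited non-normalized probe intensities on a linear scale for 25697 probes. Values down to -14.06 showed that a background had been subtracted from these deposited intensities before deposit. The authors also deposited a detection p-value for each probe and array, and how it was computed is not given in the sources used here. GenomeStudio is named in the submitters' processing notes, without a version. A further deposited table held intensities that the authors had normalized between arrays. On each array these values ranked the probes exactly as the non-normalized ones did (Spearman correlation of 1), on a linear scale and without centring per gene. Their medians per array lay between 5.298 and 5.32, and the normalization method is not given in the sources used here. This table served as an alternative source of values.

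Probes were named through the platform annotation, in which 23978 probes had 1 gene symbol, 0 had several and 1719 had none. Of the named probes, 23962 received the current symbol through their Entrez identifier in the naming table of the mouse assembly GRCm38.p6, and 16 kept the symbol of the annotation. The naming table served for symbols only. No genome build is named in the labels or the deposited files, so no coordinates are given.

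The non-normalized intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. A probe was kept if its detection p-value was under 0.05 on both arrays of at least 1 group, which kept 11761 probes, 709 of them unnamed. For the 2153 genes with several kept probes, the probe with the highest mean log2 intensity over all arrays stood for the gene, which left 7947 genes. The number of arrays limits the precision. Between 11012 and 11478 probes per array were detected, or 42.9% to 44.7% of all probes.

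A linear model with 1 mean per group was fitted to all 8 arrays with lmFit and eBayes (4 residual degrees of freedom, prior degrees of freedom 7.21). It gave 6 comparisons, which were each single treatment and the combination against DMSO, the combination against each single treatment, and the interaction. The interaction is the log2 effect of the combination minus the sum of the log2 effects of the single treatments. Calls rest on limma's two-sided moderated test with Benjamini-Hochberg adjustment within a comparison at 0.05. A gene not above background on any array of a group has only a bound there. Its change is then given as at least N-fold, the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. No fold is given where both groups were below background, and the bounds were not computed for the interaction.

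30 gene lists were written from textbook knowledge before the data were examined, together with the tests, the alternatives and the rule for named genes. 26 lists had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with a correlation estimated for each list. With an estimated correlation camera also tests on the 4 residual degrees of freedom, so the runs differ in more than the correlation. The 4 lists of other cell types, which are T and NK cells, myeloid cells, erythroid cells with platelets, and stroma with endothelium, had too few measured genes to test. List members were also counted when adjusted over the list alone.

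By the rule, the text names for each comparison against DMSO the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, and 5 and 5 for the other comparisons, with no condition on overlap for the interaction. Symbols of the clone, accession or predicted-gene type were passed over. From each list the rule adds up to 4 members with the smallest adjusted p. Of these members, and of the fixed genes below, the text gives only a part in each comparison. A gene without a value may therefore still have been called. The rule also adds a set of genes fixed in advance, of which 1 is withheld and left out here. The others are Brd2, Brd3, Atr, Chek1, Myc, Hexim1, Serpini1, Hist2h2be, Bcl2, Bcl2l11, Cdkn1a, Cdkn2a, Ddit3, Trib3, Atf4, Hspa5, Il6, Ccl5 and Cdk6. The annotation used here listed no probe for Brd3, Atr or Hist2h2be, and the probes of Serpini1 and Il6 were not kept.

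Comparisons against DMSO share 2 control arrays, and 100 sets of unchanged groups were simulated with the measured spread per gene to give the correlation, covariance and overlap of calls that arise with no effect. The fit was tested on simulated data for the 7947 genes, with 200 genes changed in each of 20 runs. For the combination against DMSO it recovered 91% of genes changed by 1 log2 unit and 45.2% of those given a smaller change. Of its calls 4.11% were unchanged genes. For the interaction it recovered 65.4% of genes changed by 1 log2 unit. The changes were added to normalized values, so background correction and normalization were not part of the test. A change in most genes was not simulated either, so the share of false calls applies to sparse changes only.

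Alternatives tried were quantile normalization without background correction, an offset of 50, median scaling, the authors' normalized values, no filter on detection, detection p-values under 0.01 on all arrays, every kept probe in place of 1 per gene, a trended and robust variance, only the arrays compared, the replicate number as a block, each array left out in turn, and the estimated correlation for lists. The files used here give no slide for an array, so the slide was not tried as a block. With 2 arrays per group no test for outlying samples and no other split of the samples was run. Nearly identical histone genes, and nearly identical Pramel genes, can share signal on a probe, so the level of an individual member is uncertain. The probe for Myc matches the mouse gene, and the sources used here do not say whether the Myc that drives these cells has that sequence.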

Results

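Transcript levels were measured in λ820 cells, a mouse lymphoma line driven by Myc, after 24 h with DMSO, with 10 µM RVX2135, with 10 µM VE-821 or with both drugs at those doses. RVX2135 inhibits BET bromodomain proteins, the readers of acetylated histones such as Brd2. VE-821 inhibits ATR, the kinase that answers stalled replication forks, in part through Chek1. The series asks whether such drugs act synergistically, and names DNA damage, apoptosis, the senescence-associated secretory programme and stress of the endoplasmic reticulum (ER) as outcomes. Each group had 2 arrays, and n = 2 per group holds for every value below. Between 11012 and 11478 of 25697 probes were detected per array, the median background-subtracted intensity over tested genes was 97.8 to 151.2, and 7947 genes were tested. Replicate arrays correlated at 0.995 to 0.996 over these genes. The median standard error (SE) of a log2 fold change was 0.117, and 0.165 for the interaction.

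The groups separated on the leading principal components. The first carried 66.1% of the variance and placed DMSO at -30.3 and -29.3, the single treatments between -8.74 and -5.08, and the combination at 44.1 and 41.6. The second carried 17.7% and separated RVX2135 (-19.0 and -20.1) from VE-821 (18.8 and 19.7).

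**Figure D1:**
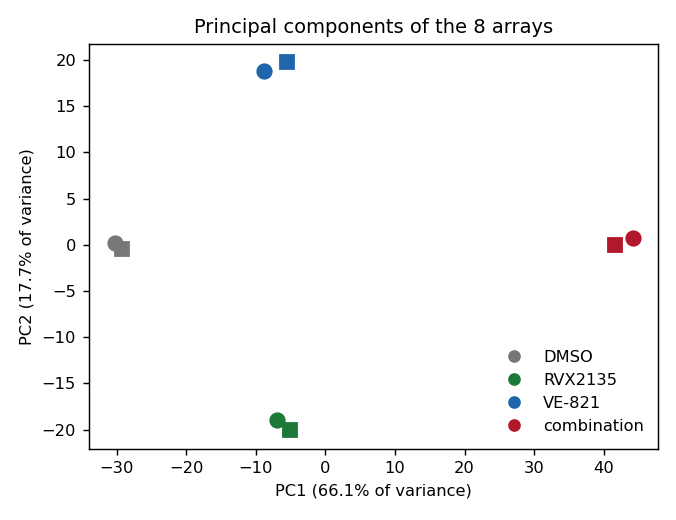
Principal components of the 8 arrays, with the first component (66.1% of the variance) on the x axis and the second (17.7%) on the y axis, in units of the component scores. Colours mark the groups, circles replicate 1 and squares replicate 2, and the combination arrays lie at 44.1 and 41.6 on the first component, against -30.3 and -29.3 for DMSO.

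RVX2135 alone lowered B lineage genes. Fcrla, an intracellular Fc receptor-like protein of B cells, fell by 4.49 on the log2 scale (SE 0.12, limma adjusted p = 2.91e-09), or 22.4-fold. Fcmr, the Fc receptor for IgM, fell by 4.21 (SE 0.18, adjusted p = 7.12e-08), and Vpreb3, a protein of the pre-B-cell receptor pathway, fell at least 21.3-fold (adjusted p = 8.58e-09). Of the 27 measured B lineage genes, 19 fell, 3 rose and 5 were not called, with a median of -0.94 (-0.88 with genes below background at their bound), and 24 were called when adjusted over the list alone. The list was lower by camera (adjusted p = 1.96e-11), but not with the correlation estimated from the data (adjusted p = 0.194 with an estimated correlation). Among the other large falls were Rsph1 (-3.84, SE 0.11), Sla (-2.74), the thrombomodulin gene Thbd (-2.71), Adam19 (at least 6.21-fold) and Rasgrp1 (at least 4.57-fold), an exchange factor for Ras. Of the 7 plasma cell genes 5 fell and 2 were not called, among them Irf4 at -1.01 and Slamf7 at -1.65 (camera adjusted p = 0.00534, adjusted p = 0.307 with an estimated correlation). With detection required on all arrays, the plasma cell call was lost (adjusted p = 0.114). Markers of other cell types, too few to test as lists, included Pecam1 at -1.02, Fbln1 at -0.61, Prf1 at 0.55 and Cd2 at -1.08, whose call was lost with the authors' values and with quantile normalization without background correction (adjusted p = 0.264 each).

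The largest rises with RVX2135 were of Pik3ip1, a negative regulator of PI3 kinase, at 2.46 (SE 0.18, adjusted p = 3.93e-06), of the linker histone H1f2 at 2.45 (SE 0.13) and of the immediate early gene Egr1 at 2.44 (SE 0.13). Jun rose at least 4.74-fold, and Ddit3, which encodes the stress factor CHOP, rose 5.1-fold (log2 2.35, SE 0.18). Histone genes formed the list with the largest median, 1.28, as 29 of 41 rose, 4 fell and 8 were not called (34 called when adjusted over the list alone). H2bc4 (2.11) and H2bc18 (1.97) were among them, and H4c18, a histone gene outside the list, rose by 2.06. Near-identical histone genes can share a probe's signal. Camera called the histone list higher (adjusted p = 8.9e-14, adjusted p = 0.237 with an estimated correlation). Of 19 genes of cholesterol synthesis, 13 rose and none fell, with Hmgcs1, which makes the HMG-CoA of the pathway, at 1.15 (SE 0.10) and Msmo1 at 1.07 (camera adjusted p = 2.62e-06, adjusted p = 0.237 with an estimated correlation). 14 of the 19 were called when adjusted over the list alone. Of 29 lysosomal genes 16 rose and 4 fell, with the autophagy receptor gene Sqstm1 at 1.27 and the protease gene Ctsh at -1.19 (camera adjusted p = 0.000437, adjusted p = 0.318 with an estimated correlation).

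Genes of DNA replication fell together with RVX2135. Of 39 S phase genes 35 fell, none rose and 4 were not called (36 called when adjusted over the list alone), with a median of -0.64. The licensing factor Cdc6 fell by 1.01 (SE 0.11), Dut by 1.02 and Uhrf1 by 1.01 (camera adjusted p = 1.73e-15, adjusted p = 0.194 with an estimated correlation). In the G2 and mitosis list 13 of 30 fell and none rose, with Kif23 at -0.97 (camera adjusted p = 4.29e-05, adjusted p = 0.331 with an estimated correlation). Of 41 genes for replication stress and repair 21 fell and 1 rose, including Chek1 at -0.90 (SE 0.11, adjusted p = 0.000184) and Clspn at -0.89 (camera adjusted p = 1.44e-06, adjusted p = 0.237 with an estimated correlation). Of 41 Myc-linked genes of ribosome biogenesis and growth 17 fell and 1 rose, with Srm at -0.79 (camera adjusted p = 8.94e-05, adjusted p = 0.276 with an estimated correlation). Hexim1, an inhibitor of the elongation factor P-TEFb, rose by 1.23 (SE 0.11, 2.35-fold, adjusted p = 1.45e-05), and Brd2 rose by 0.65 (SE 0.11). Myc itself was 0.41 higher (SE 0.11, adjusted p = 0.02), a call that was lost without DMSO replicate 1 (adjusted p = 0.106), DMSO replicate 2 (0.0649) or RVX2135 replicate 2 (0.136).

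Several lists named by the aims of the series did not pass with RVX2135 alone, although single members did. The p53 target list had 11 genes higher and 3 lower of 33 (camera adjusted p = 0.0706), with Gadd45a at 2.00 (SE 0.15), Plk2 at 1.73 and the pro-apoptotic gene Bbc3 2.84-fold higher. The integrated stress response list, the ATF4 and CHOP targets, had 16 higher and 3 lower of 43 (adjusted p = 0.0523), with Chac1 at 2.13 and Atf4 at 0.84 (SE 0.12). Senescence regulators had 8 higher and 4 lower of 21 (adjusted p = 0.151), with the cyclin-dependent kinase inhibitors Cdkn2b at 1.61 and Cdkn1b at 1.22. Secretory genes of senescence had 4 higher and 5 lower of 25 (adjusted p = 0.997), with Angptl4 at -2.16. The interferon-stimulated list had 4 higher and 7 lower of 32 (adjusted p = 0.583), with Samd9l at -1.71 and Parp14 at -1.66. RVX2135 called 2420 genes, 1196 higher and 1224 lower, of which 141 and 124 changed at least 2-fold. The count fell to 1426 without DMSO replicate 1 and to 1475 without RVX2135 replicate 2.

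**Figure D2:**
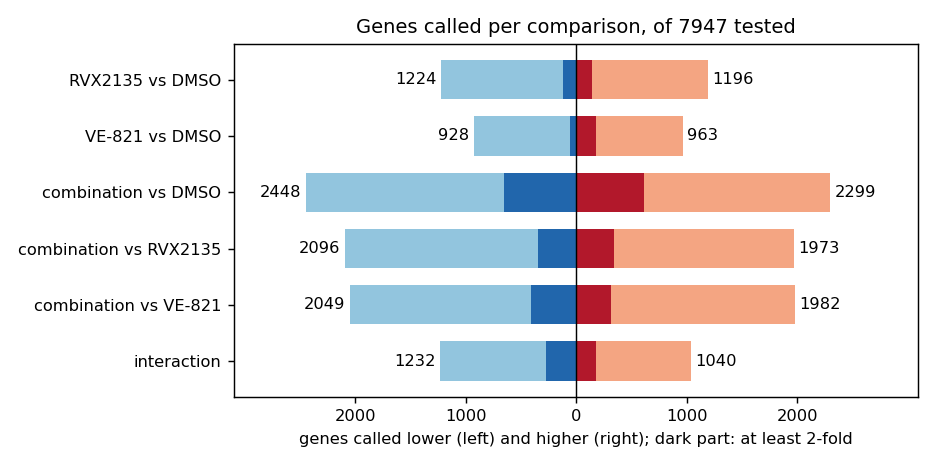
Number of genes called higher (right, red) and lower (left, blue) in each of 6 comparisons among 7947 tested genes, with the part changed at least 2-fold in the dark shade. The combination against DMSO has the longest bars, 2299 higher and 2448 lower, and VE-821 against DMSO the shortest, 963 and 928.

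VE-821 alone raised genes of the integrated stress response as its most uniform change. Of 43 measured members 38 rose, none fell and 5 were not called, with a median of 0.84, and 40 were called when adjusted over the list alone. Nupr1 rose at least 12.9-fold, Ddit3 10.2-fold (log2 3.34, SE 0.18, adjusted p = 3.1e-07), Chac1, which degrades glutathione, 9.72-fold, and Atf5 8.97-fold. Trib3 rose by 2.47 (SE 0.15) and Atf4 by 1.59 (SE 0.12). The list was called by camera (adjusted p = 1.37e-29) and kept its call with an estimated correlation (adjusted p = 0.00516). Cox6a2, a respiratory chain subunit known from muscle, had the largest rise with VE-821, 4.52 (SE 0.10, 23-fold, adjusted p = 3.37e-10), and Lrrc14b rose by 3.22 (SE 0.21).

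Inflammatory genes rose as well with VE-821. The chemokine gene Cxcl10 rose by 4.02 (SE 0.24, 16.2-fold, adjusted p = 5.72e-07). Of 22 targets of NF-kappaB 19 rose and none fell, with a median of 1.43 (1.37 with genes below background at their bound). These included the feedback inhibitor Tnfaip3 at 3.05 (SE 0.13), Relb at 2.86, Nfkbie at 2.59 and Nfkb2 at 2.29. When adjusted over the list alone 19 of the 22 were called, and the list was higher by camera (adjusted p = 2.6e-21, adjusted p = 0.0899 with an estimated correlation). Of 32 interferon-stimulated genes 22 rose, 1 fell and 9 were not called, with a median of 0.63 (0.55 at the bounds), led by Isg15 at 3.09 (SE 0.20) and Oasl1 at 2.62 (SE 0.15), while Usp18 rose at least 3.32-fold. Camera gave adjusted p = 1.35e-12, and adjusted p = 0.125 with an estimated correlation, and 24 of the 32 were called when adjusted over the list alone. The DMSO arrays differed for some of these genes, with an SD of 0.60 for Cxcl10 and 0.52 for Isg15. It was 0.23 for Oasl1 and 0.04 for Usp18, which was at background there. In the senescence-associated secretory list 11 of 25 rose and 2 fell, with Ccl5 at 2.14 (SE 0.17) and Vegfa at 1.59 (camera adjusted p = 0.000125, adjusted p = 0.0899 with an estimated correlation). The median of that list was 0.29, and 0.04 with genes below background at their bound. In the myeloid list, too small to test, Fcgr3 was 1.19 (adjusted p = 0.000177) and Tyrobp 0.62 (adjusted p = 0.00346), and both calls were lost with the authors' normalized values (adjusted p = 0.203 and 0.0556).

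With VE-821, histone genes were again higher, 28 of 41 with 2 lower (median 0.95), led by H2bc4 at 2.93 (SE 0.15), H2bc11 at 2.25 and H1f2 at 2.16 (camera adjusted p = 6.15e-14, adjusted p = 0.151 with an estimated correlation). Lysosomal genes were higher in 16 of 29 and lower in 1, with Sqstm1 at 2.15 and Ctsh at -0.87 (camera adjusted p = 2.5e-05, adjusted p = 0.225 with an estimated correlation). Cell cycle genes fell, 21 of 39 in S phase with Rrm2, a subunit of ribonucleotide reductase, at -1.08 and Tk1 at -1.12 (camera adjusted p = 2.2e-08, adjusted p = 0.151 with an estimated correlation). In G2 and mitosis 19 of 30 fell and none rose, with Ccnf at -0.82 (camera adjusted p = 2.05e-09, adjusted p = 0.225 with an estimated correlation). 15 of 41 genes for replication stress and repair fell and none rose, with Clspn at -0.82 (camera adjusted p = 8.42e-05, adjusted p = 0.225 with an estimated correlation). Chek1 was -0.26 and not called (adjusted p = 0.124). Genes of cholesterol synthesis fell in 9 of 19 and rose in none, with Lss at -0.76 and Hmgcs1 at -0.65 (camera adjusted p = 0.000225, adjusted p = 0.225 with an estimated correlation). Of 27 B lineage genes 15 fell and 4 rose, with Vpreb3 at -2.31 and Cd79b at -1.31 but the costimulatory receptor Cd40 at 1.82 (camera adjusted p = 0.00019, adjusted p = 0.225 with an estimated correlation). The largest falls outside the lists were of Klf2 (-2.50, SE 0.14), Rasgrp1 (at least 4.73-fold), Adam19 (-2.10), Ahnak (-2.02), Arhgef18 (-1.97), Thbd (-1.91) and Serpinb1a (-1.88).

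Weaker list calls with VE-821 depended on single arrays. Anti-apoptotic genes were higher in 4 of 11 (camera adjusted p = 0.0466, adjusted p = 0.238 with an estimated correlation), with Birc3 at 1.38, and the call was lost without VE-821 replicate 1 (adjusted p = 0.0829) or DMSO replicate 2 (0.0786). ER chaperones and degradation genes were higher in 9 of 32 (camera adjusted p = 0.0485, adjusted p = 0.207 with an estimated correlation), with Sel1l at 0.93 and Xbp1 at 0.91, and the call was lost without DMSO replicate 1 (0.0935) or VE-821 replicate 1 (0.0829). Ribosomal protein genes were higher in 4 of 34 (camera adjusted p = 0.0298, adjusted p = 0.174 with an estimated correlation), a call lost without DMSO replicate 1 (0.098) or VE-821 replicate 1 (0.0738). The pro-apoptotic list did not pass (4 higher and 6 lower of 21, adjusted p = 0.994), though Pmaip1, which encodes NOXA, rose by 2.07 (SE 0.12), Bbc3, which encodes PUMA, by 1.33 and Bcl2l11, which encodes BIM, by 0.77. The p53 target list did not pass either (13 higher and 5 lower of 33, adjusted p = 0.173). Cdkn1a was 0.39 higher (adjusted p = 0.0317), a call lost without DMSO replicate 1 (0.123), VE-821 replicate 1 (0.165), DMSO replicate 2 (0.119) or VE-821 replicate 2 (0.0707). Hexim1 fell by 0.48 (adjusted p = 0.00816), a call lost without DMSO replicate 2 (0.0519) or VE-821 replicate 2 (0.0833). VE-821 called 1891 genes, 963 higher and 928 lower, and 182 and 58 changed at least 2-fold. This count fell to 931 without VE-821 replicate 2, 1016 without DMSO replicate 1 and 1175 without DMSO replicate 2, and it was 1155 with the authors' values and 1194 with quantile normalization without background correction.

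**Figure D3:**
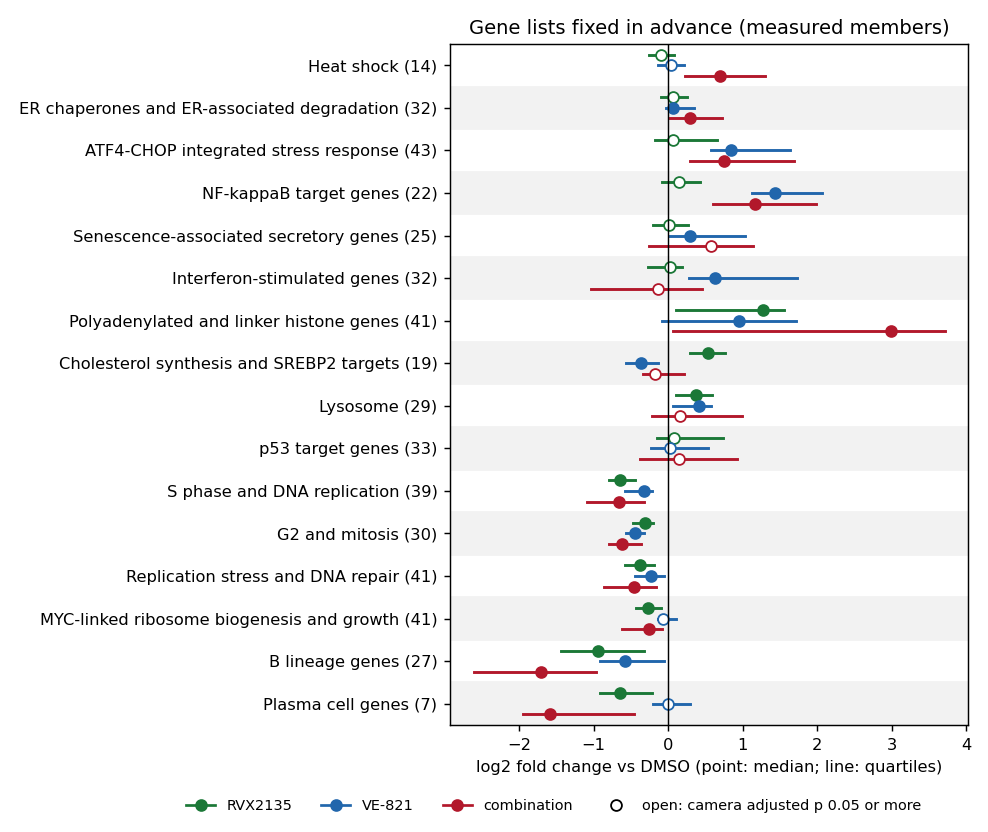
Median log2 fold change against DMSO (x axis, points) and quartiles over members (lines) of 16 gene lists (y axis, measured members in brackets), for RVX2135 in green, VE-821 in blue and the combination in red. Filled points passed camera at the preset correlation, and the histone list reached the highest median, 2.99 in the combination, and the B lineage list the lowest, -1.71.

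The combination raised stress genes strongly. Ddit3 rose 60.6-fold (log2 5.92, SE 0.18, adjusted p = 7.54e-10), and Atf3 rose by 3.71 (SE 0.14), Trib3 by 3.23, Chac1 by 3.18, Atf5 by 3.03 and Atf4 by 2.20 (SE 0.12). Of 43 integrated stress response genes 32 rose, none fell and 11 were not called, with a median of 0.75 (0.72 at the bounds) and 33 called when adjusted over the list alone. Camera called the list (adjusted p = 2.71e-10), also with an estimated correlation (adjusted p = 0.0431). Hspa5, the ER chaperone BiP, rose by 2.03 (SE 0.12, 4.07-fold, adjusted p = 1.09e-07). Of 32 genes for ER chaperones and degradation 16 rose and 4 fell, with Sel1l at 2.03 and Dnajb2 at 1.92 but the translocon-associated gene Tram1 at -2.27 (camera adjusted p = 0.0115, adjusted p = 0.21 with an estimated correlation). Of 14 heat shock genes 10 rose and 1 fell, with Hspa1a at least 22.3-fold higher, Hspb1 at 4.27 (SE 0.19) and Hsph1 at 1.52 (camera adjusted p = 0.000924, adjusted p = 0.21 with an estimated correlation). Of 23 targets of the oxidative stress factor NRF2 14 rose and 4 fell, with the haem oxygenase gene Hmox1 at 1.63 (camera adjusted p = 0.0159, adjusted p = 0.236 with an estimated correlation). That call was lost with detection required on all arrays (adjusted p = 0.3) or with every kept probe tested (0.289).

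Histone genes had the largest list median in the combination, 2.99, with 29 of 41 higher, 7 lower and 5 not called (36 called when adjusted over the list alone). Among histone genes, not all of them in the list, H4c18 rose by 5.44 (SE 0.13, 43.3-fold) and H4c12 by 5.02. H2bc8 rose by 4.81, H4c11 by 4.52 and the linker histone H1f1 by 4.31. The same reserve applies on signal shared between near-identical genes. Camera gave adjusted p = 2.71e-10 for the histone list, and adjusted p = 0.21 with an estimated correlation. Pramel37 (5.10, SE 0.21) and Pramel39 (at least 29.7-fold), members of the PRAME-like family that is active in germ cells and early embryos, and the circadian and immune repressor gene Nfil3 (4.53, SE 0.10) completed the largest rises. Of 22 NF-kappaB targets 17 rose and none fell, with Relb at 2.83, Nfkbia at 2.82 and Nfkb2 at 2.24 (camera adjusted p = 7.56e-07, adjusted p = 0.21 with an estimated correlation). The senescence-associated secretory list had 14 of 25 higher and 6 lower, with Cxcl1 at least 8.42-fold, Cxcl2 at least 4.21-fold and Ccl4 at least 3.58-fold higher, Ccl5 at 1.14 (SE 0.17) and Angptl4 at -2.87. As a list it did not pass camera (adjusted p = 0.0522), and its median was 0.57, or 0.43 at the bounds. Only 25 of its 74 genes with a probe were measured. Cxcl2, for example, was not above background with DMSO or VE-821, so the counts can lean towards rises. Interferon-stimulated genes were split, 9 higher and 14 lower of 32 (adjusted p = 0.359), from Cxcl10 at 3.99 (SE 0.24) to Samd9l at -2.73 (SE 0.16) and Parp14 at -2.23. For Irgm1, at 1.52, a second probe was called the opposite way at -1.49.

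Of 27 B lineage genes 24 were lower in the combination than in DMSO and 3 higher (median -1.71). Fcrla fell 77.9-fold (log2 -6.28, SE 0.12, adjusted p = 6.93e-11), Fcmr by 4.37, Vpreb3 by 3.87, the receptor subunit Cd79b by 3.52 and the transcription factor Ikzf1 by 3.35 (camera adjusted p = 2.93e-09, adjusted p = 0.21 with an estimated correlation). Of 7 plasma cell genes 6 fell and 1 rose, with Irf4 at -2.23 and Slamf7 at least 7.78-fold lower (camera adjusted p = 0.0105, adjusted p = 0.339 with an estimated correlation), a call lost with detection required on all arrays (adjusted p = 0.0725). In the list written for T and NK cells, too small to test, the perforin gene Prf1 was at 2.87 (SE 0.13, adjusted p = 8.19e-09) and Cd2 at least 3.3-fold lower. Large falls outside the lists included Rsph1 (-4.65), Clec2d (at least 15.5-fold), Tmem229b (-4.08), Reln (-4.02) and the proton channel gene Hvcn1 (-3.80, SE 0.10).

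Proliferation genes were lower in the combination than in DMSO. Of 39 S phase genes 32 fell, 3 rose and 4 were not called (35 called when adjusted over the list alone), with Tk1 at -2.60 (SE 0.12), E2f2 at -2.27 and Uhrf1 at -1.64 (camera adjusted p = 7.56e-07, adjusted p = 0.21 with an estimated correlation). In G2 and mitosis 23 of 30 fell and 1 rose, with Cdc25b at -1.55 and Kif11 at -1.36 (camera adjusted p = 4.19e-05, adjusted p = 0.339 with an estimated correlation). Of 41 genes for replication stress and repair 25 fell and 4 rose, with Rad54l at -1.28, Xrcc6 at -1.25, Clspn at -1.18 and Chek1 at -0.91 (camera adjusted p = 0.00137, adjusted p = 0.339 with an estimated correlation). Of 41 Myc-linked growth genes 21 fell and 6 rose, with Ldha at -1.27 (camera adjusted p = 0.0105, adjusted p = 0.347 with an estimated correlation). Glycolytic genes fell in 10 of 18, with Pdk1 at -1.34, but the glucose transporter gene Slc2a1 was 1.29 higher (camera adjusted p = 0.0333, adjusted p = 0.448 with an estimated correlation). The glycolysis call was lost without combination replicate 1 (adjusted p = 0.0503) or DMSO replicate 2 (0.0683). Myc was 0.58 higher (SE 0.11, adjusted p = 0.00106).

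Genes tied to apoptosis and senescence changed in both directions in the combination. The pro-apoptotic list did not pass (5 higher and 9 lower of 21, camera adjusted p = 0.337), with Pmaip1 at 1.39 (SE 0.12) and Bbc3 at 0.92 but Casp8 at -1.15, and Bcl2l11 was -0.11 (adjusted p = 0.375). The probes of Bcl2l11 disagreed, so its direction in the combination is uncertain. Against RVX2135 the chosen probe was called at -0.337 and other probes at 1.69 and 0.996. Against VE-821 the chosen probe was called at -0.882 and other probes at 0.784 and 0.735. Bcl2 was at least 1.27-fold lower (adjusted p = 0.00172). The p53 target list did not pass (16 higher and 9 lower of 33, adjusted p = 0.241), with Gadd45a at 2.96 and Cdkn1a, which encodes p21, at 1.10 (SE 0.11, adjusted p = 7.84e-06), while Ptp4a3 was -2.84. Senescence regulators had 8 higher and 11 lower of 21 (adjusted p = 0.835), with the cell cycle inhibitors Cdkn1c at 3.20 (SE 0.12) and Cdkn2b at 2.56, Ets1 at -1.83, and Cdkn2a at -0.11 (adjusted p = 0.422). Brd2 rose by 1.45 (SE 0.11), whereas Hexim1 was 0.51 lower than in DMSO (SE 0.11, adjusted p = 0.00164). The combination called 4747 genes, 59.7% of those tested, with 2299 higher and 2448 lower, and 615 and 652 changed at least 2-fold. Over the arrays left out in turn this count stayed between 4012 and 4765. Of the called genes 48.4% were higher, and 55% with median scaling. Before normalization the median intensity over tested genes was 151.2 and 123.2 with DMSO, and 114.3 and 97.79 with the combination. Scaling between arrays evens out a shift shared by most genes, so the balance of rises and falls cannot show such a shift.

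**Figure D4:**
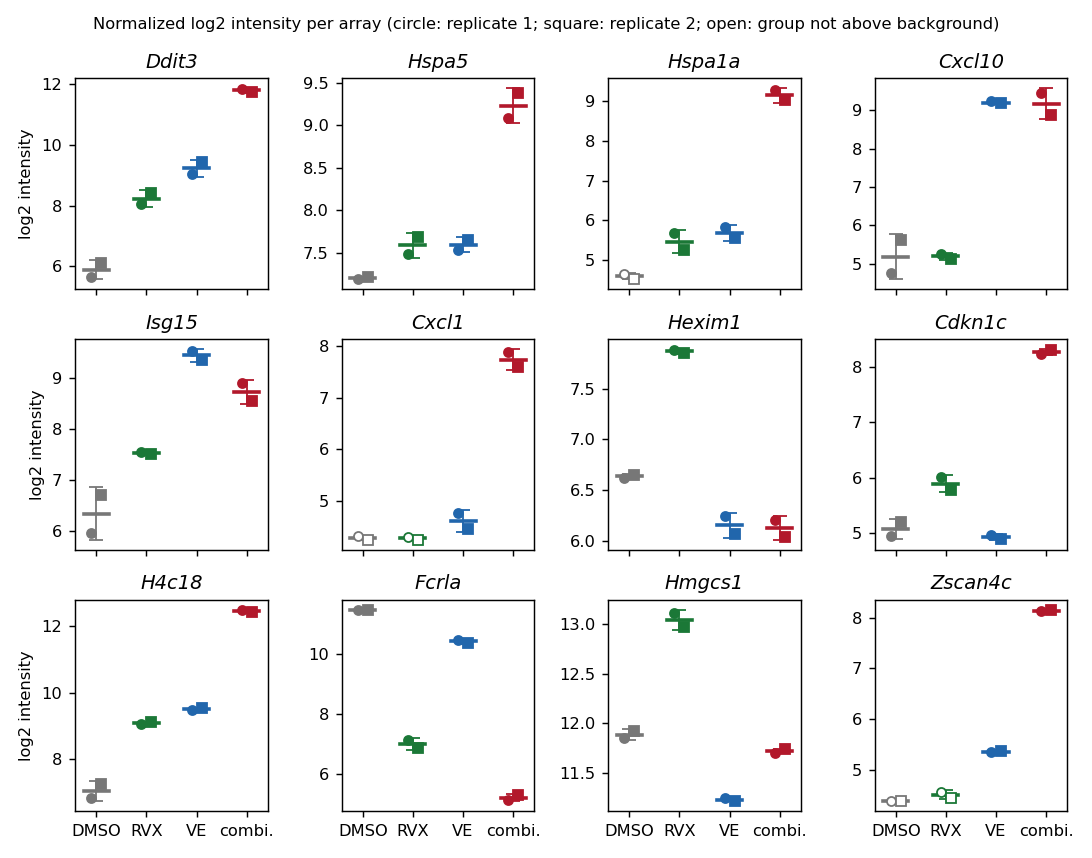
Normalized log2 intensity (y axis) of 12 genes on each array of the 4 groups (x axis: DMSO, RVX2135, VE-821, combination), with a bar at the group mean and error bars of 1 SD (n = 2); circles are replicate 1, squares replicate 2, and open symbols mark groups not above background. Ddit3 rises 5.1-fold, 10.2-fold and 60.6-fold above DMSO, Hexim1 is highest with RVX2135, and Fcrla falls 77.9-fold in the combination.

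Against RVX2135 alone, adding VE-821 raised stress genes and lowered sterol genes. Ddit3 was 11.9-fold higher (log2 3.57, SE 0.18, adjusted p = 7.31e-08), Trib3 was 2.38 higher, Hspa5 1.64 and Atf4 1.36. Pramel39 (4.88, SE 0.15), Pramel37 (4.84), Cxcl10 (3.98) and Hspa1a (3.67) rose most, and Zscan4c, a gene of the early embryo, rose at least 10.8-fold. Of 43 integrated stress response genes 34 rose and 2 fell (camera adjusted p = 5.54e-11), a call kept with an estimated correlation (adjusted p = 0.036). Heat shock genes rose in 12 of 14, with Hspb1 at 3.12 (camera adjusted p = 7.81e-06, adjusted p = 0.273 with an estimated correlation). NF-kappaB targets rose in 15 of 22, with Relb at 2.67 and Cd40 at 2.43 (camera adjusted p = 1.06e-06, adjusted p = 0.273 with an estimated correlation). Histone genes rose in 27 of 41 and fell in 6, with H2bc3 at 3.12 and H1f1 at 2.95 (camera adjusted p = 1.14e-08, adjusted p = 0.296 with an estimated correlation). Of 19 cholesterol synthesis genes 15 fell and none rose, with Stard4 at -1.76 (SE 0.10) and Hmgcs1 at -1.31 (camera adjusted p = 3.84e-05, adjusted p = 0.311 with an estimated correlation). Hexim1 fell by 1.75 (SE 0.11, 3.35-fold, adjusted p = 3.07e-07).

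The largest falls against RVX2135 were of Acss1, a mitochondrial acetyl-CoA synthetase, at -3.30 (SE 0.13, 9.84-fold), the desaturase gene Scd2 at -2.86, Reln at -2.81, Tmem229b at -2.74 and Lrmp at -2.66. B lineage genes fell in 17 of 27 and rose in 4, with Cd79b at -2.64 and Pou2af1 at -2.57 (camera adjusted p = 0.00165, adjusted p = 0.348 with an estimated correlation). ER genes rose in 16 of 32, with Creld2 at 1.24 (camera adjusted p = 0.0314, adjusted p = 0.273 with an estimated correlation). The secretory list rose in 12 of 25 and fell in 6, with Cxcl1 at least 8.19-fold higher (camera adjusted p = 0.0302, adjusted p = 0.273 with an estimated correlation), a call lost without the detection filter (adjusted p = 0.11), with detection required on all arrays (0.307) or with the authors' values (0.0507). Glycolytic genes fell in 11 of 18 (camera adjusted p = 0.0293, adjusted p = 0.542 with an estimated correlation), a call lost without RVX2135 replicate 1 (0.0503). Plasma cell genes fell in 5 of 7 (camera adjusted p = 0.0446, adjusted p = 0.52 with an estimated correlation), a call lost without either DMSO array (0.0502 each). Chek1 did not differ detectably (-0.01, adjusted p = 0.924). Of the 4069 genes called, 1973 were higher and 2096 lower.

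Against VE-821 alone, adding RVX2135 lowered interferon-stimulated and B lineage genes and raised heat shock and histone genes. Parp14 fell by 3.12 (SE 0.11, adjusted p = 8.99e-09), Samd9l by 3.02, Gbp3 by 1.82 and Usp18 at least 3.28-fold. Of 32 interferon-stimulated genes 27 fell, 2 rose and 3 were not called (29 called when adjusted over the list alone), with a median of -1.23, or -1.19 at the bounds (camera adjusted p = 2.07e-09, adjusted p = 0.297 with an estimated correlation). Fcrla fell 37.6-fold (log2 -5.23, SE 0.12), Fcmr 15.4-fold (log2 -3.95), Rsph1 9.11-fold, the peptide transporter gene Slc15a3 8.75-fold and Clec2d at least 8.65-fold. B lineage genes fell in 22 of 27 (camera adjusted p = 6.6e-10, adjusted p = 0.297 with an estimated correlation), and all 7 plasma cell genes fell, with Fkbp11 at -2.03 (camera adjusted p = 0.000155, adjusted p = 0.329 with an estimated correlation). The largest rises were of Hspb1 (12.2-fold, SE of the log2 value 0.19), Hspa1a at 3.45, Cdkn1c at 3.34, Pramel39 at 3.30 and Pramel37 at 3.14. Heat shock genes rose in 11 of 14 (camera adjusted p = 8.7e-05, adjusted p = 0.297 with an estimated correlation) and histone genes in 29 of 41, with H4c11 at 2.58 (camera adjusted p = 2.14e-10, adjusted p = 0.329 with an estimated correlation).

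Other genes also differed between the combination and VE-821. Ddit3 was 2.58 higher (SE 0.18), Hspa5 1.63, Brd2 1.19 and Gadd45a 2.10, while Ccl5 was lower (SE 0.17, adjusted p = 0.000537), Angptl4 was -2.91 and Chek1 was -0.65. In the lists written for other cell types Prf1 was 2.21 higher, Pecam1 was -1.32, and Cd2 was at least 2.08-fold, Fcgr3 at least 2.41-fold and Tyrobp at least 1.46-fold lower. The integrated stress response list did not pass (11 higher and 14 lower of 43, camera adjusted p = 0.85). S phase genes fell in 20 of 39, with Tk1 at -1.48 (camera adjusted p = 0.00162, adjusted p = 0.408 with an estimated correlation), and Myc-linked growth genes in 18 of 41, with Pes1 at -1.27 (camera adjusted p = 0.00453, adjusted p = 0.446 with an estimated correlation). Glycolytic genes fell in 10 of 18 (camera adjusted p = 0.0301, adjusted p = 0.598 with an estimated correlation), a call lost without VE-821 replicate 1 (0.0619) or combination replicate 1 (0.0606). BET and P-TEFb genes rose in 4 of 8, with Ccnt1 at 0.73 (camera adjusted p = 0.0489, adjusted p = 0.408 with an estimated correlation), a call lost without combination replicate 1 (0.0962) or VE-821 replicate 2 (0.0988). NRF2 targets rose in 10 of 23 (camera adjusted p = 0.0489, adjusted p = 0.408 with an estimated correlation). That call was lost without DMSO replicate 1 (0.0541), DMSO replicate 2 (0.0541), VE-821 replicate 1 (0.0597), VE-821 replicate 2 (0.062), combination replicate 1 (0.0606) or combination replicate 2 (0.052). Of the 4031 genes called, 1982 were higher and 2049 lower.

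Of all 7947 genes, 1398 were higher than with either drug alone, and 1375 were lower than with either. The former included 26 of 41 histone genes, 11 of 14 heat shock genes, 8 of 23 NRF2 targets, 11 of 32 ER genes and 11 of 43 integrated stress response genes. The latter included 14 of 27 B lineage genes, 8 of 18 glycolytic genes, 12 of 32 interferon-stimulated genes, 12 of 39 S phase genes and 5 of 7 plasma cell genes. Independent lists of the same sizes would share 492.1 and 540.4 genes, and unchanged groups that share the combination arrays shared 0 on average over 100 simulations. The former values leave out the shared combination arrays and the simulation leaves out the effects, so no excess over either is called a shared effect. A further 123 genes lay higher than one single treatment and lower than the other. Against DMSO, 2193 genes were called in the combination and in neither single treatment, and 861 of these were also called in the interaction.

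The interaction tested whether the combination departed from the sum of the single effects on the log2 scale. Heat shock genes lay above the sum in 11 of 14 and below in none (median 0.92, 11 called when adjusted over the list alone), with Hspa1a at 2.57 (SE 0.22, adjusted p = 2.36e-05), Hspb1 at 2.45, Hsph1 at 1.76 and Dnajb1 at 1.18 (camera adjusted p = 5.32e-07, adjusted p = 0.288 with an estimated correlation). Hspa5 lay 1.25 above the sum (SE 0.17, adjusted p = 0.00054). Interferon-stimulated genes lay below it in 24 of 32 and above in 1 (median -1.10, 29 called when adjusted over the list alone), with Ifit3 at -2.77 (SE 0.29, adjusted p = 8.13e-05) and Usp18 at -1.77 (camera adjusted p = 5.02e-11, adjusted p = 0.288 with an estimated correlation). Ifit3 differed between the DMSO arrays (SD 0.44). The genes farthest above the sum were Pramel39 (3.19), Cxcl1 (3.13, SE 0.19), Vpreb3 (3.09), Pramel37 (2.88) and Zscan4c (2.64, SE 0.14). Pramel39, Cxcl1, Zscan4c and Hspa1a were not above background with DMSO, and Usp18 was not with DMSO or the combination, so their values and their order rest in part on background-level signal. Vpreb3 was at background with RVX2135, and the sum of its single effects lies below the background level, so even a background signal in the combination would lie above the sum and its value is no evidence of a departure. Farthest below after Ifit3 were Lrrc14b (-2.68), the adaptor gene Blnk (-2.39), the stress gene Ddit4 (-2.31) and Cox6a2 (-2.30).

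Of the stress genes that rose with all treatments, Ddit3 (0.23, SE 0.25, adjusted p = 0.536), Trib3 (-0.09, adjusted p = 0.787) and Atf4 (-0.23, adjusted p = 0.332) did not depart detectably from the sum. Chac1 lay below it (-2.23, SE 0.16). Hexim1 lay at -1.26 (SE 0.15), Ccl5 at -1.68 (SE 0.24), Bbc3 at -1.91 and Cdkn1c at 2.52. Bcl2l11 was called at -1.11, but another of its probes was called the opposite way at 0.553. Cdkn1a lay at 0.60 (adjusted p = 0.0179), a call lost without DMSO replicate 1 (0.0534), RVX2135 replicate 1 (0.0501), VE-821 replicate 2 (0.0647) or combination replicate 2 (0.0552). Brd2 lay at 0.53 (adjusted p = 0.0228), a call lost without DMSO replicate 1 (0.0933), VE-821 replicate 1 (0.0616), combination replicate 1 (0.0642), VE-821 replicate 2 (0.0571) or RVX2135 replicate 2 (0.077). Chek1 (0.25, adjusted p = 0.275), Myc (-0.18, adjusted p = 0.429) and Bcl2 (0.30, adjusted p = 0.213) were not called.

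S phase genes lay above the sum in 11 of 39 and below in 1, with Cdc6 at 0.88 (camera adjusted p = 0.00362, adjusted p = 0.46 with an estimated correlation). Lysosomal genes lay below in 10 of 29, with Gusb at -1.30 (camera adjusted p = 0.00362, adjusted p = 0.46 with an estimated correlation), as did 6 of 7 plasma cell genes, with Fkbp11 at -1.22 (camera adjusted p = 0.00363, adjusted p = 0.46 with an estimated correlation). Histone genes lay above in 15 of 41 and below in 4, with H2ac4 at 1.86 (camera adjusted p = 0.0233, adjusted p = 0.475 with an estimated correlation), a call lost without combination replicate 1 (0.0509) or DMSO replicate 2 (0.0659). NF-kappaB targets lay below in 8 of 22 and above in 3 (camera adjusted p = 0.0233, adjusted p = 0.46 with an estimated correlation), a call lost without combination replicate 2 (0.127). Genes for replication stress and repair lay above in 7 of 41 and below in 1 (4 called when adjusted over the list alone; camera adjusted p = 0.0297, adjusted p = 0.46 with an estimated correlation). Their call was lost without DMSO replicate 1 (0.0854), VE-821 replicate 1 (0.0561), RVX2135 replicate 2 (0.0751) or combination replicate 2 (0.0546). Cholesterol synthesis genes lay below in 6 of 19, with Stard4 at -1.33 (camera adjusted p = 0.0259, adjusted p = 0.46 with an estimated correlation), a call lost without DMSO replicate 1 (0.0854), VE-821 replicate 1 (0.0549) or combination replicate 1 (0.0855). Glycolytic genes lay below in 5 of 18, with Pdk1 at -1.03 (camera adjusted p = 0.0259, adjusted p = 0.46 with an estimated correlation), a call lost without DMSO replicate 1 (0.0843), VE-821 replicate 1 (0.0537), RVX2135 replicate 1 (0.0693) or combination replicate 1 (0.0598). In all, 2272 genes were called, 1040 above and 1232 below the sum. Of these, 1499 departed in the direction of a called combination effect and 239 against it. The count was 1474 with quantile normalization without background correction and 1440 with the authors' values.

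More genes were called in the same direction by pairs of treatments than in independent lists, counted across genes, which are not independent replicates. RVX2135 and VE-821 both raised 420 genes and both lowered 440, against 144.9 and 142.9 for independent lists and 0 on average in simulated unchanged groups, and 112 genes were called in opposite directions. Their log2 fold changes correlated at 0.476, against 0.499 for simulated unchanged groups that share the DMSO arrays, and the covariance was 0.086 against a simulated 0.00931, a difference of 0.0767. RVX2135 and the combination correlated at 0.672 (simulated 0.5) with a covariance of 0.236 (simulated 0.00929), both raised 794 genes (346 for independent lists, 0 simulated) and both lowered 953 (377 and 0). VE-821 and the combination correlated at 0.661 (simulated 0.5) with a covariance of 0.228 (simulated 0.00932), both raised 700 genes (278.6 and 0) and both lowered 771 (285.9 and 0). Part of the excess of the overlaps over independent lists may come from the shared controls, which were not split because each part would keep 1 array. The simulated covariances already hold the shared controls at the measured spread, which may be technical. No excess is called a shared effect. The correlation of RVX2135 with VE-821 did not exceed its simulated value, but that value comes from groups whose changes are spread alone. It lies near 0.5 whatever the size of the spread, so it cannot show whether the effects of the drugs were alike. In all 3 treatments 795 genes were called in the same direction.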

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

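Of the tests below, those of a general loss in the combination and of signal shared between histone genes were chosen only after the result was seen, and the list of early-embryo genes was written after the largest changes had been seen.

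A difference between groups drew attention to 2272 genes, for which the effect of RVX2135 differed with and without VE-821 by limma's test of the interaction. Camera called 10 lists for the interaction at the preset correlation, and 0 of them with an estimated correlation. Of these lists, those with a median above the sum of the single effects were heat shock (0.92), S phase and DNA replication (0.24), replication stress and DNA repair (0.24) and histone genes (0.22). Those below were interferon-stimulated genes (-1.10), plasma cell genes (-0.65), NF-kappaB targets (-0.36), lysosome (-0.35), cholesterol synthesis (-0.24) and glycolysis (-0.23). Among single genes the interaction was 3.19 for Pramel39, 3.13 for Cxcl1, 3.09 for Vpreb3, 2.88 for Pramel37, 2.64 for Zscan4c, 1.25 for Hspa5, 0.60 for Cdkn1a and 0.53 for Brd2. It was -1.11 for Bcl2l11, -1.26 for Hexim1, -1.68 for Ccl5, -2.30 for Cox6a2, -2.31 for Ddit4, -2.39 for Blnk, -2.68 for Lrrc14b and -2.77 for Ifit3. Pramel39, Cxcl1 and Zscan4c were not above background with DMSO, so their values rest in part on background-level signal, and the sign of the Vpreb3 value is forced by the background level, which lies above the sum of its single effects. A signal in data outside the comparisons of named genes came from 413 of 709 kept probes with no gene name, of which 219 were higher and 194 lower in the combination than in DMSO, beside 59.7% of named genes called in that comparison.

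Interferon-stimulated genes were called higher as a list with VE-821 (camera adjusted p = 1.35e-12, adjusted p = 0.125 with an estimated correlation), but not with the combination, where 9 of 32 were higher and 14 lower (adjusted p = 0.359). Other ways of scaling or background correction would have to bring the median interaction near 0, and the nearest of 4 was -0.75, against -1.10. A general loss in the combination of the transcripts that VE-821 raised would have lowered other such genes as well. The 941 raised genes outside the list had a median of 0.17 in the combination against VE-821. Of these 257 were called lower, beside 2049 of all 7947 genes. The 22 raised list members had a median of -1.36 (permutation p = 1e-05, the smallest these permutations can give, which takes the genes as independent). The list's camera call against VE-821 had adjusted p = 0.297 with an estimated correlation. With VE-821 the list members had risen more (median 1.03 against 0.55), and the sets were not matched on that rise. A loss limited to strongly raised transcripts was therefore not tested. The added drug, RVX2135, is the difference in the design, and how it acted was not tested.

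Histone genes rose with the combination (camera adjusted p = 2.71e-10, adjusted p = 0.21 with an estimated correlation) while S phase genes fell, and the share of cells in S phase was not measured. Signal shared between core histone genes alone would have spared the 4 linker histone genes, whose median was 3.09. H1f1 rose by 4.31, H1f2 by 3.19, H1f5 by 2.99 and H1f10 by 1.13. Sharing between core genes thus does not account for the rise of the linker genes. Whether core histone probes share signal cannot be told from these values, since both could hold together. Over 4 other ways of scaling or background correction the median of the histone list stayed at 2.36 or above, against 2.99. Histone transcripts with a poly(A) tail may have been labelled in place of those without, but the priming is not given in the sources used here and this was not tested.

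Zscan4c and Pramel39 were detected with the combination and not with DMSO, and both were also detected with VE-821. If a wider early-embryo programme were active, other such genes would be detected as well, and 9 of 22 others were detected on both combination arrays and on no DMSO array, which does not decide the question. The share of all probed genes with this pattern is not given here, so 9 of 22 cannot be read as many or few. Other ways of scaling or background correction left the fitted log2 value of Zscan4c at 2.52 or above, against 3.75, which rests on background signal in DMSO (a rise of at least 11.1-fold).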

How the results depend on the processing

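Of 66 list calls none turned direction under any alternative, and 63 were lost with the correlation estimated from the data, which left 0 lists with RVX2135, 1 with VE-821, 1 with the combination, 1 for the combination against RVX2135, 0 against VE-821 and 0 for the interaction. That setting also tests on the 4 residual degrees of freedom, so these 63 losses cannot be put down to the correlation alone. Of the list calls 11 were lost with detection required on all arrays, 10 with the authors' values, 8 with quantile normalization without background correction, 4 with median scaling, 4 with every kept probe, 3 without the detection filter, 2 with offset 50, 1 of 56 with only the arrays compared and 0 with the trended and robust variance, and 35 of 528 with an array left out. Of 689 calls of named genes 52 were lost with quantile normalization without background correction, 55 with the authors' values, 24 without the detection filter, 23 with median scaling, 14 with offset 50, 7 with the trended and robust variance, 7 of 585 with only the arrays compared, 6 with every kept probe, 0 of 505 with detection required on all arrays, and 236 of 5512 with an array left out. Cdk6 turned in the combination against DMSO with median scaling (0.004, adjusted p = 0.983), with both groups below background. The cause of these losses was not tested. Where a further probe and the chosen probe of a gene were both called, some went opposite ways. These were 72 of 1450 for the combination against DMSO, 76 of 1121 against RVX2135 and 70 of 1067 against VE-821. They were 18 of 382 for the interaction, 4 of 562 with RVX2135 and 1 of 363 with VE-821. For the histone gene H2bc18 the interaction was -1.57 on the chosen probe and 1.27 on another, so its place below the sum is uncertain.

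Genes called with VE-821 numbered 1194 with quantile normalization without background correction and 1155 with the authors' values, against 1891, and the interaction called 1474 and 1440, against 2272. With an array left out, and a lone array taken to vary like the others, RVX2135 called 1426 to 2493 genes and VE-821 931 to 1975. The correlation of RVX2135 with VE-821 (0.476) was then 0.45 to 0.524, that of RVX2135 with the combination (0.672) 0.655 to 0.682, and that of VE-821 with the combination (0.661) 0.63 to 0.672. In the same order of pairs these were 0.417, 0.634 and 0.585 with quantile normalization without background correction, 0.414, 0.631 and 0.579 with the authors' values, and 0.497, 0.688 and 0.678 with median scaling. RVX2135 with VE-821 gave 0.498 with offset 50 and 0.5 with detection required on all arrays, RVX2135 with the combination 0.664 without the detection filter and 0.67 with every kept probe, and VE-821 with the combination 0.687 with offset 50 and 0.688 with detection required on all arrays. The causes were not tested.

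The replicate number used as a block, which would treat arrays as paired, gave 2481, 1976, 4825, 4183, 4115 and 2319 calls in the 6 comparisons, and 5 of the 689 calls of named genes and 2 of the 66 list calls were lost. Differences between replicates correlated at -0.0312 to 0.178 between groups. The labels give replicate 1 the letter A and replicate 2 the letter B without saying what the letters mark, so pairing is not established. The slide block was not run, nor was the interaction with only the arrays compared, which needs all 8.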

Other observations

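Some early-embryo and PRAME-like genes were detected with the combination and not with DMSO. Zscan4c, a marker of the 2-cell embryo, was not above background with DMSO or RVX2135, was detected on both VE-821 arrays, and rose at least 11.1-fold with the combination (adjusted p = 3.14e-10). Tcstv3, Tdpoz5, Zfp352, Usp17la, Usp17lb, Usp17lc, Obox7 and Arg2 were detected on both combination arrays and on no other array, and Tcstv1 on both combination arrays and 1 RVX2135 array. Of the others, Tdpoz1 and Tdpoz2 were detected on both DMSO arrays, Tdpoz4 on 1 VE-821 and 1 combination array, and Sp110 on every array but those of the combination, while Tdpoz3, Usp17ld, Tmem92, Obox1, Obox2, Obox3, Obox6, Pramel6 and Pramel7 were detected on none. These genes were chosen after the values were seen. Among PRAME-like genes Pramel12 and Pramel37 were detected on all arrays and Pramel39 on both VE-821 arrays, while Pramel20 rose at least 4-fold and Pramel31 at least 3.48-fold with the combination. Pramel12 rose by 0.54 (adjusted p = 0.00507).

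The following lists did not pass in the combination against DMSO, where 59.7% of all genes were called. Of 21 HDAC, sirtuin and SWI/SNF genes 12 were lower and 4 higher (camera adjusted p = 0.237), with the deacetylase gene Hdac7 at least 3.03-fold lower, the remodeller gene Smarca4 at -1.11 (SE 0.12) and Sirt1 at 1.35 (SE 0.14). Of 9 genes of the MYC/MAX network 4 were lower and 1 higher (adjusted p = 0.558), with Max at -0.78. Of 34 genes of the mitochondrial respiratory chain 9 were lower and 3 higher (adjusted p = 0.359). Of 29 lysosomal genes 12 were higher and 5 lower (adjusted p = 0.181), with Laptm4a at 2.02 and Gusb at -2.03. Cholesterol synthesis genes were lower in 6 of 19 and higher in 3 (adjusted p = 0.392). In the list written for stroma and endothelium Pecam1 was -1.77 (SE 0.16) and Fbln1 -0.94, and the erythroid gene Klf1 was -0.17 (adjusted p = 0.219).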
